A study of Mus musculus with 4 samples.

How the data were processed

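Gene counts of 4 libraries were analysed, 2 from control (Ctrl) and 2 from Ell3 knockdown (Ell3 KD) mouse GV oocytes. Each library was made from 5 oocytes with a Smart-seq2 protocol, amplified for 16 cycles and sequenced as 150-bp paired-end reads, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. How the knockdown was made, and whether replicates came from separate animals or days, was not given in the sources used here.

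The deposited values are raw counts, whole numbers of reads or fragments per gene symbol. Per the submitters' processing notes, FastQC 0.11.5, HISAT2 2.2.1.0 and featureCounts (no version given) were used with genome build mm10. The annotation, the strand setting and the handling of reads that map to several places or genes were not given in the sources used here. Without these settings, reads of overlapping genes, paralogs and pseudogene copies cannot be assigned with certainty. Each file held 53677 gene symbols, 28301 of them with a count in at least 1 library.

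Library totals were 45131278 and 48669267 counts in Ctrl and 89632815 and 65722415 in Ell3 KD. A count of 0 allowed a level of up to 0.0665, 0.0616, 0.0335 and 0.0456 CPM in these libraries, in the same order, taking 3 counts as the limit. Chi-square tests of the counts within each group gave 4.08 per degree of freedom in Ctrl and 4.17 in Ell3 KD. These tests cover counting error only, which separately amplified libraries are bound to exceed, and the libraries were analysed separately as the labels give them.

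Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr with the groups, TMM factors, estimateDisp, glmQLFit, glmQLFTest, two-sided) on all 4 libraries without covariates. TMM factors lay between 0.984 and 1.015. Of the genes, 17879 passed the filter. Values of p were adjusted by the Benjamini-Hochberg method over all genes tested, and genes were called at an adjusted p under 0.05. Standard errors were the log2 fold change divided by the square root of its F statistic, and 95% intervals used the t quantile at the 26.3 total degrees of freedom of the fit. Mean ± SD are of CPM scaled by the TMM factors. Log2 CPM for correlations and for list tests other than those of DESeq2 and limma-voom used a prior count of 2.

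The genes named in the text, the 24 gene lists, the tests and the first set of alternatives were fixed before the data were examined. The rule named Ell3, then, among genes past the threshold with both Ell3 KD libraries on one side of both Ctrl libraries and a mean of at least 5 CPM, the 8 largest rises and the 8 largest falls in log2 fold change. Symbols of predicted genes, of Rik clones and of pseudogenes were counted but not named. They made up 240 of the 2634 genes that met the conditions for a rise and 146 of the 2455 for a fall. From each list the rule took the 2 members with the highest mean CPM and up to 4 called members with the smallest p, and it took Gdf9, Bmp15, Zp3, Ccnb1, Mos, Ell and Ell2 as anchors. It gave 149 genes, of which the text describes a part. Genes named outside the rule are said to be singled out after their values were seen.

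Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 24 lists. Camera sets a list against all other genes tested. For DESeq2 it was run on the test statistics of the genes, without the low-count filter, rather than on log2 CPM. Its list results therefore differ from those of the main test in statistic and in background. For limma-voom, camera was run on the log2 CPM and weights of voom. The alternatives that change the filter also change the background. Members were also adjusted over their list alone. The lists covered oocyte factors, the subcortical maternal complex, meiotic kinases, the kinetochore, the spindle, cohesin and the anaphase-promoting complex, elongation factors, RNA polymerase II, maternal mRNA decay, dormant mRNAs, chromatin, recombination, p53 targets, stress responses, antioxidants, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, interferon response, RNA interference, embryonic genome activation, and markers of cumulus, theca and blood cells.

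Coordinates, exon overlaps, transcript lengths and GC content came from GENCODE mouse release M21 on GRCm38, the assembly that mm10 names. Length and GC content were those of the longest annotated transcript of each gene. Of the symbols in the files, 49804 matched a name there, and 17308 (96.8%) of those tested matched a single gene.

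The fits were tested on simulated counts drawn from the means and totals of these libraries and the dispersions of the fit for 17879 genes. In these, 200 genes were changed, and a list of 60 further genes was raised slightly. For Ell3 KD against Ctrl, edgeR called 64.2% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 86.4% of those changed 4-fold in the right direction, and 0.0284% of unchanged genes. The 95% intervals held the true change for 93.8% of the changed genes. These rates hold for the simulated setting only. In the data 42.9% of genes were called, and the spread between libraries may be technical, so error rates of the calls are not given by them.

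Alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2 within edgeR, upper-quartile factors, library totals alone, no low-count filter, a filter of 5 CPM in 2 libraries, no mitochondrially encoded genes, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, and a minimum 2-fold change. Alternatives chosen after seeing the data were thinning of all libraries to one depth, removal of each library's trend on transcript length and GC content, and a likelihood ratio test in edgeR with an assumed coefficient of variation of 0.2. No sample was left out of the main comparison.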

Results

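The series held RNA-seq libraries from mouse oocytes at the germinal vesicle (GV) stage, the stage of arrest in meiotic prophase before maturation resumes. Females received 7.5 IU of PMSG, a gonadotropin that makes follicles grow, and oocytes were taken 48 h later. There were 2 groups, control oocytes (Ctrl) and oocytes with a knockdown of Ell3 (Ell3 KD), with 2 libraries each and 5 oocytes per library. Polyadenylated RNA was amplified by Smart-seq2, a full-length cDNA method for very small inputs. The deposited counts summed to 45131278 and 48669267 in the Ctrl libraries and to 89632815 and 65722415 in the Ell3 KD libraries, so that the groups did not overlap in depth. Between 23568 and 24498 genes had at least 1 count per library. A gene with no count in a library lay below 0.0665 CPM (counts scaled to a total of 1e+06) in the shallowest library and below 0.0335 CPM in the deepest, taking 3 counts as the limit. These limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

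Ell3 encodes a member of the ELL family of RNA polymerase II elongation factors and was the targeted gene. It was lower in both Ell3 KD libraries, with counts of 255 and 181 against 371 and 483 in Ctrl. This was 2.84 ± 0.0558 CPM in Ell3 KD against 8.95 ± 1.18 CPM in Ctrl (SD, n = 2 per group, as for every CPM value that follows), 3.15-fold lower. The log2 fold change was -1.66 ± 0.14 (SE; edgeR adjusted p = 6.04e-10). The gene lies on chromosome 2 from 121439010 to 121444278 on the minus strand of GRCm38. Of its exon length, 65.6% is shared with Serinc4 on the same strand. Serinc4 itself had 8 and 5 counts in Ctrl and 11 and 11 in Ell3 KD, so few reads were credited to it. Whether reads in the shared exons were left out or credited to Ell3 was not given in the sources used here. Such reads therefore cannot be assigned to one of these genes with certainty. Of its paralogs, Ell fell by 0.21 ± 0.04 on the log2 scale (edgeR adjusted p = 3.44e-05), and Ell2 had a log2 fold change of 0.02 ± 0.08 that did not pass the test (edgeR adjusted p = 0.876).

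The submitters gave the comparison of Ell3 KD with Ctrl as a look for an effect on transcription that bears on meiosis. Among genes that met the naming rule (called, at 5 CPM or more, with predicted, Rik and pseudogene symbols left out), the largest rise was that of Spp1. It encodes the secreted phosphoprotein osteopontin. Spp1 went from 0.558 ± 0.0155 to 15.4 ± 0.602 CPM, a log2 fold change of 4.78 ± 0.16 (edgeR adjusted p = 1.10e-18). The largest fall under the same rule was that of Xdh, which encodes xanthine dehydrogenase of purine breakdown. Xdh went from 49.8 ± 0.456 to 2.29 ± 0.136 CPM, 21.9-fold lower, with a log2 fold change of -4.45 ± 0.08 (edgeR adjusted p = 1.99e-24). Of 17879 genes tested, 3770 were higher and 3906 lower in Ell3 KD, and the changes were mostly small, with a median absolute log2 fold change of 0.38 among the genes called. The scaling of the libraries centers the changes near 0 (median -0.0024 over all genes tested). All changes are therefore relative to the other genes of a library, and a change in total mRNA per oocyte would not be seen.

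The kinase gene Dapk3 rose 8.81-fold, from 5.22 ± 0.0133 to 46.0 ± 2.32 CPM (log2 fold change 3.14 ± 0.08, edgeR adjusted p = 1.01e-21). Genes for a pair of small GTPases at the plasma membrane rose to high levels: Arf6 from 32.8 ± 2.01 to 131.4 ± 0.678 CPM and Rac1 from 83.2 ± 0.053 to 328.1 ± 5.32 CPM, with log2 fold changes of 2.00 and 1.98. Tmem158, the stress-induced regulator Nupr1, the Hedgehog pathway transcription factor Gli3 and Pthlh, which encodes a parathyroid hormone-like hormone, rose by log2 fold changes of 2.31, 2.04, 1.98 and 1.82. Besides Xdh and Ell3, the genes that fell most under the naming rule, at 5 CPM or more, were the olfactory receptor gene Olfr1257 (-1.58), the fatty acid desaturase gene Scd3 (-1.52), Plxdc2 (-1.50), Ero1l (-1.47), an oxidoreductase gene of disulfide bond formation, Tcp11l2 (-1.31) and the mitochondrial carrier gene Slc25a30 (-1.29). For these genes the highest edgeR adjusted p was 2.78e-09. That both Ell3 KD libraries lay on one side of both Ctrl libraries was a condition of naming them. Exons of Rac1 overlap those of Daglb on the opposite strand over 51.4% of their length, and how the counting treated strand was not given in the sources used here. Daglb, examined after its value was seen, went from 342.4 ± 7.55 to 295.0 ± 4.31 CPM, so the added Rac1 counts were not matched by a rise of Daglb. Exons of Spp1 (18.8% of their length), Arf6 (13.6%), Dapk3 (8.37%) and Gli3 (1.96%) also overlap annotated genes, and Scd3 and Olfr1257 belong to families of similar copies, which makes their counts less certain. On GRCm38, Spp1 lies on chromosome 5 from 104435118 to 104441050, Xdh on chromosome 17 from 73883895 to 73950196, Dapk3 on chromosome 10 from 81183005 to 81193197 and Rac1 on chromosome 5 from 143503634 to 143528036.

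**Figure D1:**
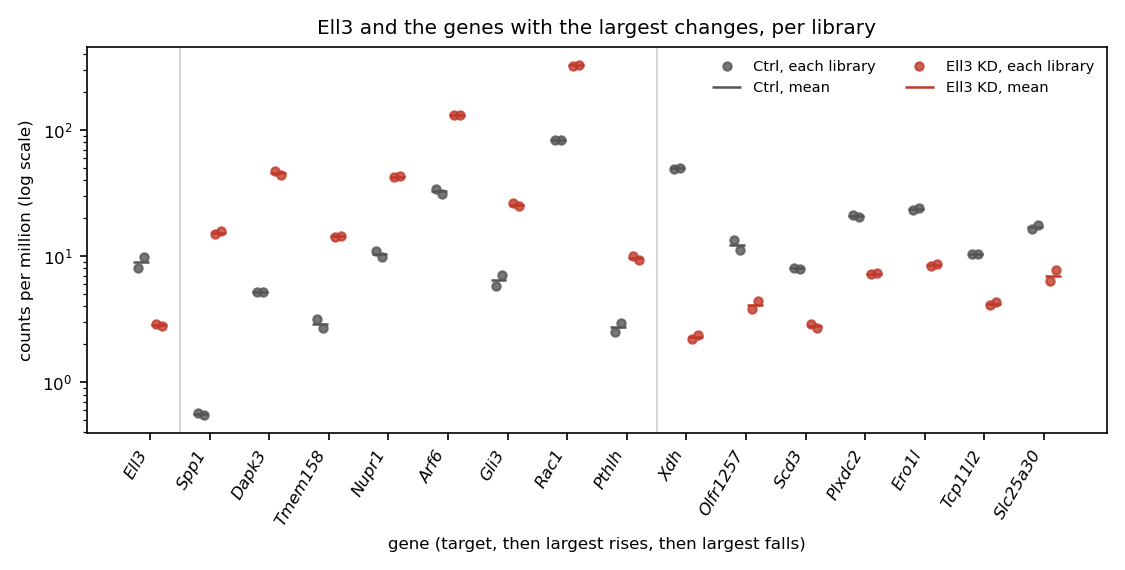
CPM (log axis) of Ell3, the 8 genes with the largest rise and the 7 others with the largest fall under the naming rule, each point a library and each bar the mean of a group's 2 libraries. Xdh lies at 49.8 CPM on average in Ctrl and at 2.29 CPM in Ell3 KD, and Spp1 at 0.558 and 15.4 CPM.

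Changes of at least 2-fold were called for 748 genes that rose and 930 that fell, and 1282 of these 1678 genes had a mean under 1 CPM over the 4 libraries. Among the 9704 genes at 5 CPM or more, 5099 were called but only 51 by at least 2-fold, 31 higher and 20 lower. In that class the whole 95% interval of the log2 fold change lay within a 2-fold change either way for 9584 genes (98.8%), against 12323 of all genes tested (68.9%). For 67 genes without a count in Ctrl and 54 without a count in Ell3 KD the fitted fold is not a bound. All of them were called, but such a gene passes the low-count filter only by its counts in the other group, which favours a call. Pearson correlations of log2 CPM over genes were 0.990 and 0.994 within groups and between 0.970 and 0.971 across groups. The labels do not say whether libraries of a group came from separate animals. The p-values and the 95% intervals therefore rest only on the spread between these libraries, which may be technical. That spread was small, with a biological coefficient of variation of 0.0421, a single value common to all genes. With an assumed coefficient of variation of 0.2, a value chosen after seeing the data, 861 genes were higher and 1103 lower. Of these 1964 genes, 1825 were also called in the main test. At 2-fold or more this setting called 1808 genes against 1678, so it was not stricter for every gene. Under it the whole interval lay within a 2-fold change for 11210 of all genes tested, against 12323.

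**Figure D2:**
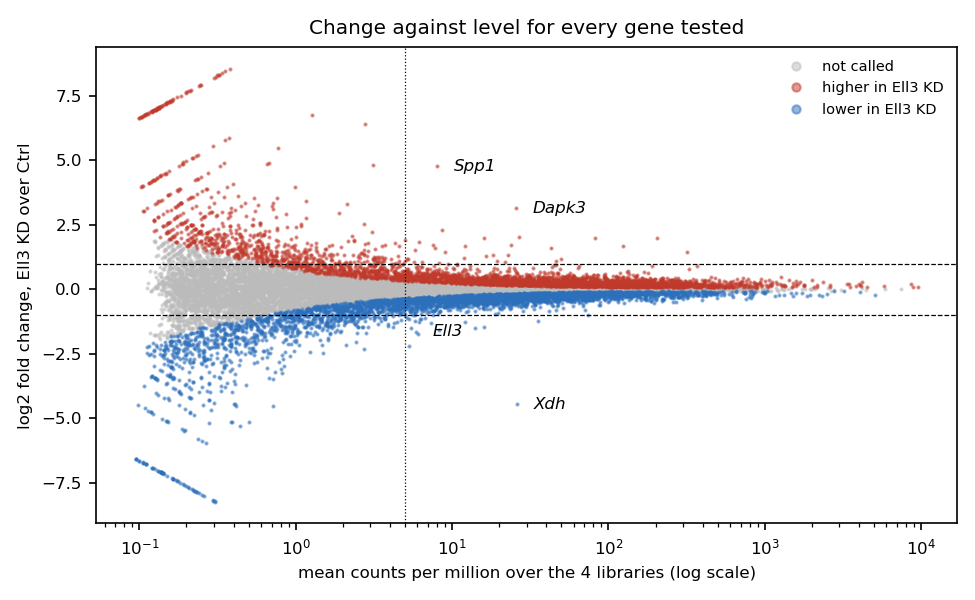
Log2 fold change (Ell3 KD over Ctrl) of each gene tested against its mean CPM over the 4 libraries (log axis), colored by the call at an adjusted p of 0.05. Dashed lines mark a 2-fold change and the dotted line 5 CPM. To the right of it, 51 called genes lie at or beyond 2-fold.

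Genes for the ribosome and for the respiratory chain were higher in Ell3 KD. Of 80 cytosolic ribosomal protein genes, 63 rose and 1 fell (66 and 1 adjusted over the list alone), with a median log2 fold change of 0.30. Rpl37 rose by 0.64 ± 0.04 and Rps29 by 0.61 ± 0.04 on the log2 scale, and the gene that fell was Rps23 (-0.22 ± 0.06), singled out after its value was seen. Without Ell3 KD replicate 1 Rps23 was not called (edgeR adjusted p = 0.0694). Of 76 nuclear-encoded genes of oxidative phosphorylation, 61 rose and 2 fell (62 and 3 adjusted over the list alone), also with a median of 0.30. Examples are Cox5b (0.53 ± 0.04), Ndufa4 (0.48 ± 0.04) and Atp5j2 (0.43 ± 0.03). The pair that fell, Uqcrc1 (-0.72 ± 0.05) and Cyc1 (-0.39 ± 0.05, singled out after its value was seen), both encode parts of complex III. Of 12 mitochondrially encoded genes tested, 10 rose and none fell (10 and 0 adjusted over the list alone), with a median of 0.38. The ribosomal RNA gene mt-Rnr2 rose from 237.4 ± 15.7 to 414.7 ± 0.337 CPM, and mt-Nd1 rose by 0.57 ± 0.06. Mitochondrially encoded genes took 0.0573% and 0.0584% of the counts in Ctrl and 0.0819% and 0.0815% in Ell3 KD. With camera's preset correlation of 0.01 the adjusted p was 7.05e-12 for the ribosomal list, 1.18e-10 for the nuclear-encoded list and 1.72e-04 for the mitochondrially encoded list. With an estimated correlation these were lost, at camera adjusted p = 0.382, adjusted p = 0.448 and adjusted p = 0.382. The estimates were 0.0380, 0.104 and -0.0297. The last lies below the preset, so a higher correlation does not account for the loss of the mitochondrially encoded list. With the assumed coefficient of variation of 0.2, 0 of the 80, 0 of the 76 and 0 of the 12 genes were called by edgeR. Of 1964 genes called under that setting, 1808 changed at least 2-fold, and the highest members of these lists rose by 0.64, 0.53 and 0.80. It could hardly call such changes, and the lists were not tested under it, so it does not bear on a joint shift. With the trend on transcript length and GC content removed, an alternative chosen after seeing the data, the medians of the lists were 0.24, 0.23 and 0.21.

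The general transcription machinery was also higher, whereas elongation factors went both ways. Of 44 genes for RNA polymerase II subunits and general transcription factors, 28 rose and 1 fell, a count that was the same adjusted over the list alone, with a median log2 fold change of 0.17. Polr2l rose by 0.48 ± 0.04, Polr2k by 0.48 ± 0.04, Gtf2b by 0.33 ± 0.03 and Polr2g by 0.33 ± 0.03, and Taf11, singled out after its value was seen, fell by 0.26 ± 0.06. The list had a camera adjusted p of 1.31e-04, and adjusted p = 0.382 with an estimated correlation. With the assumed coefficient of variation 0 of the 44 were called, but that setting could hardly call changes this small and does not bear on a joint shift. Of 47 elongation factor genes, 15 rose and 16 fell (16 and 18 adjusted over the list alone; camera adjusted p = 0.892). Besides Ell3, Aff1, a scaffold gene of the super elongation complex, fell by 0.37 ± 0.04, while Mllt3 of the same complex rose by 0.25 ± 0.04 and Ice1 of the little elongation complex rose by 0.39 ± 0.04.

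Among genes of meiosis, those of the kinetochore and the spindle assembly checkpoint were higher as a list. Of its 47 genes, 27 rose and 6 fell (29 and 7 adjusted over the list alone), with a median of 0.12. Cenpa, which encodes the centromeric histone, rose by 0.34 ± 0.04, Cenpm by 0.32 ± 0.03 and Cenph by 0.24 ± 0.03, while the checkpoint kinase gene Bub1b fell by 0.14 ± 0.03 and the Cenpa chaperone gene Hjurp by 0.44 ± 0.05. The camera adjusted p was 0.0106, and adjusted p = 0.448 with an estimated correlation. Without Ctrl replicate 1 the list was not called (camera adjusted p = 0.0702), nor without Ctrl replicate 2 (camera adjusted p = 0.0661). With the assumed coefficient of variation 0 of the 47 genes were called, though small changes of single genes could hardly be called under it. Of 36 genes of meiotic resumption and cyclic AMP arrest, 10 rose and 10 fell (10 and 11 adjusted over the list alone; camera adjusted p = 0.892). Prkaca, the catalytic subunit gene of protein kinase A, rose from 14.2 to 29.4 CPM (log2 fold change 1.05 ± 0.08), and Wee1, a kinase gene inhibiting CDK1, fell from 24.8 ± 0.173 to 12.7 ± 1.39 CPM (-0.97 ± 0.08). Cks2 rose by 0.31 ± 0.03, Plk1 fell by 0.21 ± 0.03, and cyclin B1 (Ccnb1) at 3122 ± 86.9 and 3060 ± 25.5 CPM and Mos at 505.1 and 517.6 CPM did not pass the test (edgeR adjusted p = 0.382 and adjusted p = 0.372). Of 56 genes of spindle assembly, motors and the chromosomal passenger complex, 15 rose and 10 fell, the same adjusted over the list alone (camera adjusted p = 0.892). Survivin (Birc5) rose by 0.21 ± 0.03, and Tubgcp4, with 26.1% of its exon length shared with genes on the opposite strand, fell by 0.83 ± 0.12. Of 39 genes of cohesin, shugoshin and the anaphase-promoting complex, 16 rose and 7 fell (17 and 7 adjusted over the list alone; camera adjusted p = 0.398). Securin (Pttg1), at 9183 ± 143.5 and 9870 ± 150.1 CPM, rose by 0.10 ± 0.02, and the activator and subunit genes Fzr1 and Anapc5 fell by 0.38 ± 0.04 and 0.37 ± 0.03.

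Genes of oocyte identity and of maternal stores went both ways. Of 24 genes for oocyte-secreted factors, the zona pellucida and oocyte transcription factors, 9 rose and 7 fell, the same adjusted over the list alone, with a median log2 fold change of 0.0022 (camera adjusted p = 0.892). The growth factor gene Gdf9 fell by 0.20 ± 0.03 and the transcription factor gene Taf4b by 0.76 ± 0.06, Oosp1 rose by 0.46 ± 0.03, and Zp3, at 7425 ± 20.4 and 7403 ± 53.6 CPM, and Bmp15, at 1986 ± 23.2 and 2064 ± 19.8 CPM, did not pass the test (edgeR adjusted p = 0.900 and adjusted p = 0.0832). Of 28 genes of the subcortical maternal complex and other maternal-effect genes, 13 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.217). This list was called higher by camera with DESeq2 (adjusted p = 1.28e-05) and limma-voom (adjusted p = 0.0153) and by fry (adjusted p = 0.00986), but not with an estimated correlation (camera adjusted p = 0.649). Dppa3 rose by 0.49 ± 0.03 and Ooep by 0.40 ± 0.03, and Nlrp5 fell by 0.23 ± 0.03. Of 55 genes of maternal mRNA storage, deadenylation and decay, 15 rose and 20 fell (16 and 21 adjusted over the list alone; camera adjusted p = 0.892). The deadenylation adaptor gene Btg4 rose by 0.36 ± 0.03, and the reader gene Ythdf2 and the meiosis regulator gene Marf1 fell by 0.38 ± 0.04 and 0.34 ± 0.03. Of 25 dormant maternal mRNAs recruited for translation at maturation, 13 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.416), with rises of Oosp1 and Btg4 and a fall of Wee1 among them.

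Of 59 chromatin, DNA methylation and histone modifier genes, 16 rose and 18 fell (16 and 19 adjusted over the list alone; camera adjusted p = 0.892). Smarca5, an ATPase gene of ISWI remodelers, rose from 58.8 ± 2.87 to 190.3 ± 4.41 CPM (log2 fold change 1.69 ± 0.04, edgeR adjusted p = 1.01e-21), and the demethylase gene Kdm1b fell by 0.41 ± 0.03. Of 48 homologous recombination and DNA damage checkpoint genes, 12 rose and 14 fell (14 and 15 adjusted over the list alone; camera adjusted p = 0.892). The synaptonemal complex and axis genes Sycp3 (0.92 ± 0.06), Hormad1 (0.63 ± 0.05) and Tex12 (0.61 ± 0.06) rose, and Trp73 fell by 0.56 ± 0.06. Exons of Sycp3 overlap Chpt1 on the opposite strand over 52.2% of their length, and Chpt1, examined after its value was seen, lay at 0.889 and 0.694 CPM (edgeR adjusted p = 0.481). Of 29 RNA interference and piRNA genes, 10 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.569), with Henmt1 (14.7% of exon length shared with an opposite-strand gene) rising by 0.82 ± 0.05 and Tdrd5 falling by 0.31 ± 0.03. Of 18 markers of embryonic genome activation tested, 4 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.707). Tcstv3, with a close copy in Tcstv1, rose by 0.87 ± 0.13.

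Of 36 p53 target and apoptosis genes, 11 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.389). Trp53inp1 rose by 0.47 ± 0.05, Mdm2 by 0.30 ± 0.04 and Bcl2l10 by 0.21 ± 0.03. Of 39 genes of the heat shock, unfolded protein and integrated stress responses, 9 rose and 16 fell, the same adjusted over the list alone (camera adjusted p = 0.569). Herpud1 fell by 0.65 ± 0.06, Xbp1 by 0.53 ± 0.06, Hsph1 by 0.45 ± 0.03 and Hspa5 by 0.22 ± 0.03. Of the most abundant members, Hsp90aa1 rose by 0.08 ± 0.03 (edgeR adjusted p = 0.0357) and Dnaja1 did not pass the test (edgeR adjusted p = 0.785). The call of Hsp90aa1 was lost without Ctrl replicate 1 (edgeR adjusted p = 0.330) and without Ell3 KD replicate 2 (edgeR adjusted p = 0.259). Of 28 antioxidant genes, 11 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.569). The peroxiredoxin gene Prdx1 rose from 1755 ± 6.88 to 2260 ± 40.4 CPM, and Gpx1 rose by 0.71 ± 0.09. Of 21 interferon and double-stranded RNA response genes tested, 4 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.962). Bst2 rose by 1.16 ± 0.14, and Dhx58, at 0.522 and 0.0380 CPM, fell by 3.68 ± 0.70.

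Markers of cells that could adhere to oocytes were examined in the same way. Of 26 cumulus and granulosa genes tested, 6 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.892). Gja1 rose by 1.17 ± 0.16, Inha by 1.16 ± 0.24 and Ptgs2 from 0.185 ± 0.168 to 1.32 ± 0.152 CPM, while Greb1 fell by 1.04 ± 0.20, and Serpine2 and Esr2, the most abundant members, did not pass the test (edgeR adjusted p = 0.133 and adjusted p = 0.222). The log2 fold change of Ptgs2, 2.79 ± 0.45, was 2.10 without Ctrl replicate 1 and 4.28 without Ctrl replicate 2. Of 14 theca, stroma and endothelial genes tested, 3 rose and 4 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.982), with Dcn rising by 1.12 ± 0.26 and Pecam1 falling by 0.35 ± 0.05. Of 11 blood and immune genes tested, 3 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.892), with H2-Aa rising by 0.62 ± 0.13 and Cd68 falling by 1.16 ± 0.23. Over the 24 lists, camera with the preset correlation called 5 higher and 0 lower, 0 were called with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, called 10 higher. Beyond the 5 and the maternal-effect list, fry called p53 target, antioxidant, RNA interference and theca genes higher, and camera with DESeq2 called dormant mRNAs (adjusted p = 0.00133) and antioxidant genes (adjusted p = 0.0232). Median and mean log2 fold change had opposite signs for elongation factors (0.02 and -0.03), chromatin genes (-0.05 and 0.0034), antioxidant genes (0.03 and -0.01), interferon genes (0.01 and -0.15), theca genes (0.0096 and -0.09) and blood genes (0.08 and -0.15). For spindle genes both lay below 0 (-0.00012 and -0.01) while camera pointed higher, and for meiotic resumption genes both lay below 0 (-0.01 and -0.04) while fry pointed higher.

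**Figure D3:**
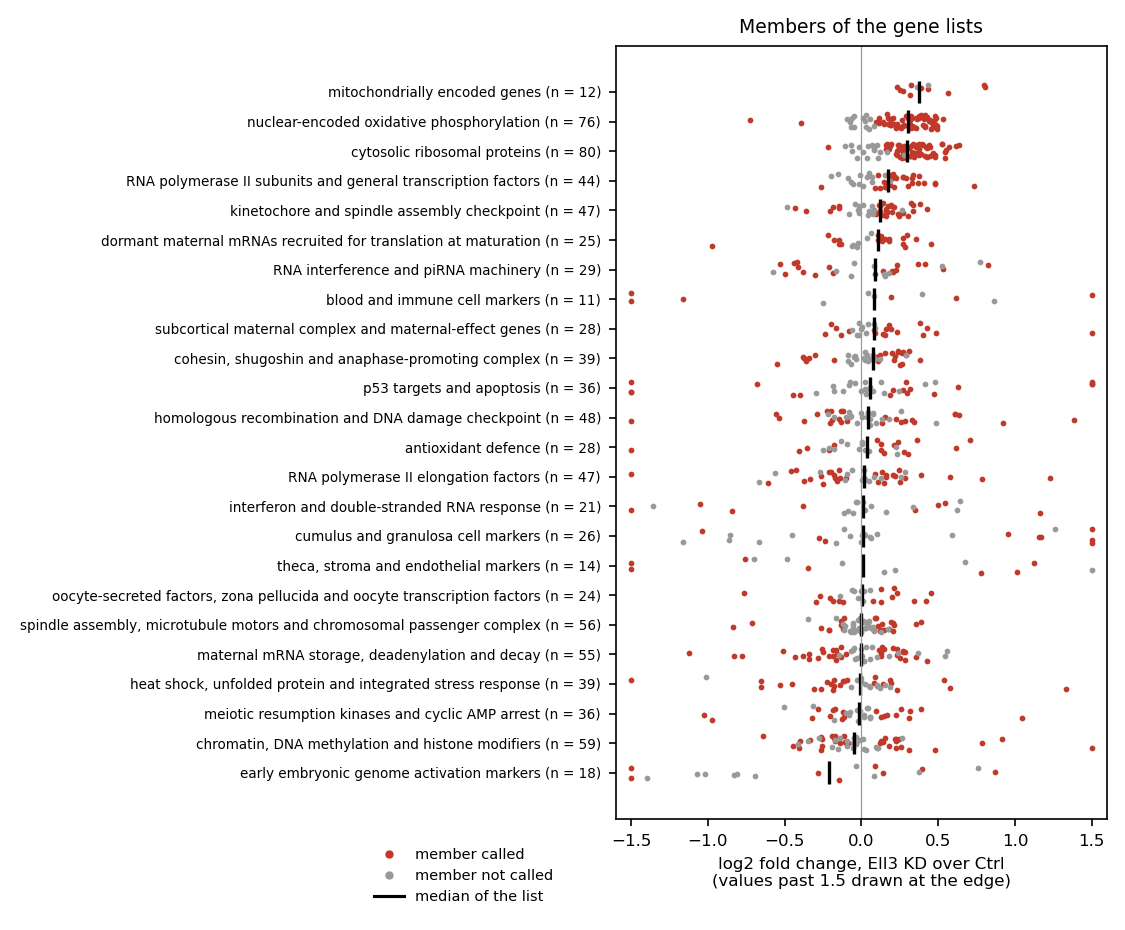
Log2 fold change (Ell3 KD over Ctrl) of every tested member of the 24 gene lists, in order of the list median (vertical bars), with called members in red. Values past 1.5 either way are drawn at the edge, and the 3 highest medians are those of mitochondrially encoded genes (0.38), nuclear-encoded oxidative phosphorylation (0.30) and cytosolic ribosomal proteins (0.30).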

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

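The alternatives reported here that were chosen only after the results were seen are thinning to one depth, removal of the length and GC trend, and the assumed coefficient of variation of 0.2. Ell3 was called lower under every alternative, with log2 fold changes from -1.79 to -1.52. Leaving out each library in turn gave 2797 to 3482 genes higher and 2922 to 3439 lower. Thinned, 3413 were higher and 3515 lower, and with the trend removed 4052 and 3474. DESeq2 shared 5250 of its 5542 calls with the 7676 of edgeR. With library totals alone 3141 were higher and 4559 lower. With an assumed coefficient of variation of 0.2 the counts were 861 and 1103, and 98 of 131 called named genes besides Ell3 lost their call. At 2-fold or more, however, 1808 genes were called with it, against 1678 in the main test. This alternative changed both the spread and the test, and their shares were not separated. At least 2-fold changes were called for 748 and 930 genes, fewer by construction.

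Lists called numbered 5 in the main test, 8 under DESeq2, 0 with an estimated correlation and 10 by fry. With an estimated correlation camera rests on the few residual degrees of freedom of 4 libraries, which leaves it little power. The estimates for the mitochondrially encoded (-0.0297) and RNA polymerase II (-0.0215) lists lay below the preset 0.01, so a higher correlation did not end their calls. The DESeq2 test used another statistic and more genes. Shares of these differences were not separated. The mean correlation within groups exceeded that between groups by 0.0210, by 0.0127 on ranks and by 0.0116 over genes at 5 CPM in 2 libraries, where low genes are left out. Over genes, the deviations of Ctrl 1 and Ell3 KD 1 from their group means had a correlation of 0.0294. With 2 libraries per group this value cannot show whether the replicate numbers mark a shared animal or day. With a replicate block 3894 genes were higher and 3987 lower.

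No gene called in both the main test and an alternative had opposite signs in them. Named genes that were not called did, and the cause was not tested. Zp3 was 0.000752 with DESeq2, 0.0034 with upper-quartile factors and 0.0081 with no filter. With library totals alone Mos was -0.00412, Ell2 -0.0209, Esco2 -0.0248, Bcl2l1 -0.012 and Irf1 -0.0174. Dnaja1 was 0.000486 with no filter. With the length and GC trend removed Padi6 was 0.032, Tacc3 0.0262, Dnaja1 0.0102 and Adar 0.0673. With libraries left out Esco2 ranged from -0.0143 to 0.0398, Irf1 from -0.0115 to 0.0513, Dnaja1 from -0.0461 to 0.0289, Zp3 from -0.00884 to 0.00738 and Ell2 from -0.0319 to 0.0786. Calls of Cenpf, Hsp90aa1, Nelfa, Sdhd, Cldn5, Elof1, Hspa1b and Zbed3 ended without at least 1 of the libraries.

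The median SE was 0.544 for genes under 1 CPM and 0.0393 at 50 CPM or more.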

Other observations

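The genes of this part were singled out after their values were seen, and the tests of the shared library, of each group as one batch, of falls of all pseudogenes, and of cumulus RNA were chosen only after the results were seen, as was the removal of depth and of length and GC trends.

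Below the level set for named genes, some changes were larger than those above it. Mmp13, a collagenase gene, rose from 2 and 4 counts to 534 and 321 (log2 fold change 6.40 ± 0.32, edgeR adjusted p = 2.24e-14). Prodh2, of proline and hydroxyproline breakdown, rose from 12 and 8 counts to 550 and 380 (4.83 ± 0.25, edgeR adjusted p = 3.75e-14). Slc22a18 rose from 8 and 11 counts to 205 and 127 (3.41 ± 0.34). Sppl2b fell from 112 and 132 counts to 62 and 11 (-2.48 ± 0.35, but -3.89 without Ell3 KD replicate 1 and -1.87 without Ell3 KD replicate 2). The aminoacyl-tRNA synthetase gene Aars2 fell from 176 and 256 to 77 and 63 (-2.30 ± 0.21).

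Death receptor and p53 target genes at low levels went both ways. Bbc3, which encodes the apoptosis inducer PUMA, had 0 counts in both Ctrl libraries and 47 and 49 in Ell3 KD, at least 10.2-fold higher with 3 counts per library as the limit (edgeR adjusted p = 4.98e-06). Tnfrsf10b had 3 and 0 counts in Ctrl and 38 and 37 in Ell3 KD (edgeR adjusted p = 3.56e-04). Fas fell from 20 and 25 counts to 8 and 3 (-2.71 ± 0.65, edgeR adjusted p = 0.00137). In the maternal-effect list, Basp1 had 0 and 2 counts in Ctrl against 75 and 33 in Ell3 KD (edgeR adjusted p = 1.98e-05). Among recombination genes, the recombinase gene Dmc1 fell from 54 and 96 counts to 19 and 20 (-2.59 ± 0.39), while the synaptonemal gene Syce1 rose from 57 and 87 to 355 and 251 (1.38 ± 0.20).

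The first pattern is the large number of called genes, 7676, most with small changes. Differences in depth and a trend on length and GC content were argued against as its cause: with all libraries thinned to one depth 6928 genes were called, and with the length and GC trend removed 7526. The variance between libraries of a group was 2.72 times the Poisson variance (95% interval 2.65 to 2.79) at 5 to 50 counts and 9.78 times (9.11 to 10.5) at 5000 or more. Chi-square per degree of freedom was 4.08 in Ctrl and 4.17 in Ell3 KD. One amplified library sequenced as both replicates of a group would differ by counting error alone if each fragment was counted once. The values exceed that error. Whether reads or fragments were counted was not given, and the error that counting added is unknown, so this test cannot decide the question. At one depth, pairs of libraries from different groups had at least 315 genes at 0 in one and at 10 or more counts in the other, against 42 in the Ctrl pair and 14 in the Ell3 KD pair. Collection or preparation of each group as one batch could give the same values and cannot be told apart from the knockdown, because the labels give no batch, and RNA pooled within a group and divided before amplification was not tested. An effect of the knockdown also stays open.

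The second pattern is the joint rise of ribosomal protein and oxidative phosphorylation genes, which have short transcripts. Their median lengths were 1076.5 and 1141 nt, taking the longest annotated transcript of each gene. Over 9521 genes at 5 CPM or more, log2 fold change fell with transcript length (Spearman rho -0.203, across genes, which are not independent replicates), and the shortest 20% of genes, up to 1791 nt, had a median of 0.12. With the trend on length and GC content removed, fitted without these lists, the medians were 0.241 (95% interval 0.193 to 0.269) and 0.237 (0.182 to 0.267). This argues against the fitted trend as the whole cause, while the trend may account for part. If the expressed transcripts are shorter than the longest annotated ones, the correction could fall short. The mitochondrially encoded list went from 0.38 to 0.225 (0.180 to 0.347), so that more of its rise could be owed to the trend. Counts moved from pseudogenes are argued against as the whole cause: 288 named copies of ribosomal protein genes, at 202.6 CPM in Ctrl, changed by 7.26 CPM, and the falls of 10963 pseudogene symbols of any gene summed to 505.4 CPM (at most 603.8 in any pair of libraries), under the gain of 1283 CPM (at least 1132). Reads that were not counted stay open. So do a difference between groups in collection, preparation or oocyte state and an effect of the knockdown.

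The third pattern is that some cumulus and granulosa genes at a low level in Ctrl were higher in Ell3 KD, although the whole list of 26 tested genes had a median of 0.01. The 20 list members under 2 CPM in Ctrl had a median log2 fold change of 0.78, at percentile 98.12 of 10000 random lists matched on level, against percentiles 68.3 for theca and 49.5 for blood genes. Without the low-count filter 7 of the 20 were called higher, among them Inha, Ptgs2 and Npr2, and 1 lower. These members were picked after they were seen to be higher, so the percentile restates the pattern and gives no support to a trace of cumulus RNA, which may or may not be its source. Fshr (41 and 50 counts against 53 and 29) went from 0.955 to 0.523 CPM and Star (34 and 43 against 40 and 37) from 0.808 to 0.512 CPM. Both point lower in Ell3 KD, opposite to the pattern, but were not called (edgeR adjusted p = 0.0679 and adjusted p = 0.209 without the filter). Expression of these genes by the oocyte itself stays open.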
